A study of Caenorhabditis elegans with 12 samples.

How the data were processed

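Whole-worm total RNA of Caenorhabditis elegans was hybridised to Affymetrix C. elegans arrays, with 1 array for each of 12 samples. Per the labels' protocols, worms were synchronised as L1 larvae by hypochlorite treatment and raised at 25 °C until they were young adults. A large-particle sorter then collected 1000 adults for each sample with a gate meant to leave out L4 and younger animals. Labelling started from 100 ng of RNA. The groups were taken from the sample titles: wild type strain N2, the temperature-sensitive allele fer-1(hc1) in strain BA1 and the temperature-sensitive allele fer-1(hc24) in strain BA24, with 4 arrays in each group. The titles call the samples biological replicates. The series description states that 6 preparations were made per genotype and that 4 were kept for their correlation within the genotype, so the spread between the arrays analysed here understates the spread between preparations, and p-values are correspondingly small.

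The authors deposited 1 log2 expression value per probe set and array. Per the submitters' processing notes these came from Affymetrix Expression Console and GCRMA, a method that corrects background from the probe sequence, normalizes across arrays and summarises the probes of a probe set on the log2 scale. The software versions are not given in the sources used here. Scanner files were not used here. The table held 22625 probe sets, of which 77 were array controls. Of the 22548 others, 20810 were paired with 1 gene symbol by the platform annotation, 843 with several and 895 with none in the table used. Gene symbols were checked by Entrez ID against a RefSeq gene table of assembly WBcel235, which held 20701 of the 1-gene probe sets, and 0 symbols changed. That table was also used for chromosome names and for gene order. No coordinates are given, because the build behind the array annotation is not given in the sources used here.

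A probe set was tested when its log2 value was at least 4 in at least 4 of the 12 arrays, which left 11833 probe sets (11274 with 1 gene, 346 with several and 213 with none) and 8761 distinct genes. Linear models were fitted to the log2 values of all 12 arrays with limma 3.58.1 in R 4.3.3, with a mean per group, no covariates and empirical Bayes moderation of the residual variance, which has 9 residual degrees of freedom before moderation. P-values were adjusted by the Benjamini-Hochberg method within each contrast, and a probe set was called changed at an adjusted p under 0.05. All adjusted p-values of single genes in the text come from this fit, are two-sided and rest on 4 arrays per group. Values are means ± SD. Where every array of a group, or its mean, lay under log2 4, that group was held at 4 and the fold is given as "at least". Depth does not apply to arrays, and their number limits the precision.

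25 gene lists were fixed before the data were examined, together with most tests, the alternatives and the rule for the named genes. Lists were tested with limma's camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over 25 lists and 3 contrasts. The brightest probe set of each gene, or of each set of genes sharing a probe set, was used (9059 in all, beside 8761 single genes). A probe set with several genes entered a list only if all were members, and then counts as 1 gene. Such probe sets make up 18 of 41 histone, 11 of 96 collagen and 5 of 27 major sperm protein entries. Camera compares a list with all other genes. Counts of list members use the adjusted p over all tested probe sets. Adjusted over the list alone, the counts were equal for 20 of 25 lists in hc1 against wild type, for 19 in hc24 against wild type and for 9 in hc1 against hc24, and differed by at most 4, 2 and 9 members in any list. Of the 75 list tests, 47 passed with the preset correlation and 0 with a correlation estimated from the residuals of each list, so the adjusted p from the estimated correlation is printed beside each list.

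Named genes had to be represented by a probe set with 1 gene. The rule took fer-1, the 8 largest rises and 8 largest falls of each mutant against wild type among called genes whose arrays did not overlap, the 6 largest rises and falls common to both alleles, the 5 largest differences each way between the alleles and, for each list and mutant, up to 2 rising and 2 falling members with the smallest adjusted p, or the 2 brightest where no member passed. It selected 143 genes, of which a part is named. The neighbours of hosl-1 and ent-5 on chromosome X lie outside this rule and were chosen after the values were seen.

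Overlaps of both mutants against the same wild type arrays were set beside 50 simulations of unchanged groups and beside the 6 ways to divide the wild type arrays between the comparisons. Single values were compared by exact two-sided permutation tests over 70 assignments of 8 arrays, whose smallest p is 0.0286. The fit was tested on simulated data built on the 11833 probe sets, with 200 changed probe sets per mutant: for a log2 change of 1 it recovered 93.5% of them in hc1 and 91.5% in hc24, and for 0.5 it recovered 62.5% and 63.5%. False calls made up 3.11% and 4.69% of calls at 1, 3.85% and 5.93% at 0.5, and 9.59% and 4.33% at 2. The simulated noise was independent between probe sets, and far fewer probe sets changed than were called in the data. Alternatives covered no filter and a stricter filter at log2 6, values under 4 set to 4, median centring, cyclic loess, a variance trend with robust moderation, fits of only the groups compared, array weights, the replicate number as a block, a threshold of at least 2-fold, fry (which tests a list against no change rather than against other genes), the mean of probe sets, an estimated correlation and leaving out each array. A list test with an estimated correlation and without hc1 replicate 2 was added after the data were seen. Array controls were used only for quality checks. Probe sets with several genes were counted and could enter lists, those with none were only counted, and neither kind was named.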

Results

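Expression was measured in young adult hermaphrodite cultures of wild type C. elegans and of 2 strains carrying temperature-sensitive alleles of fer-1, hc1 and hc24, all raised at 25 °C. fer-1 encodes a ferlin, a membrane protein of the family that includes human dysferlin, and is known for its role in the fusion of membranous organelles during sperm maturation. The comparisons ask how transcript levels in whole mutant worms differed from wild type and whether the alleles differed from each other. Each group had 4 arrays. Median log2 values over all probe sets were 4.60 ± 0.05 (SD, n = 4) in wild type, 4.35 ± 0.01 (SD, n = 4) in hc1 and 4.35 ± 0.02 (SD, n = 4) in hc24. Correlations across probe sets, which are not independent, were at least 0.989 between arrays of a group, 0.910 to 0.938 between wild type and hc1, 0.912 to 0.934 between wild type and hc24, and 0.972 to 0.981 between hc1 and hc24. The leading principal component held 71.8% of the variance and separated wild type from both mutants, and the next held 17.4% and separated hc1 from hc24.

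The only fer-1 probe set lay at background in every array. Its log2 level was 1.46 ± 0.00 in wild type, 1.48 ± 0.01 in hc1 and 1.47 ± 0.00 in hc24 (SD, n = 4 each), at the 0.0887 to 0.111 percentile of the arrays. It was therefore not tested among the 11833 probe sets and cannot check the genotype labels. An exact permutation test gave p = 0.0286 for the difference of 0.01 between hc1 and wild type, the smallest p the design allows, and p = 0.0571 for hc24. These differences lie within the floor of the measurement.

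In hc1 against wild type, lists of early embryonic and germ line genes passed as higher, and lists of the molting cycle, cuticle, muscle, neurons and intestine as lower, at the preset correlation. With an estimated correlation 0 of 25 lists passed (lowest adjusted p = 0.130), and 12 of 46 zygotic embryonic genes fell. pes-10, a gene known for transcription in the early embryo, was at background in wild type (2.58 ± 0.07) and reached 9.06 ± 0.16 in hc1 (SD, n = 4), at least 33.4-fold higher (adjusted p = 1.07e-12). dct-13 was at least 46.7-fold and pap-3 at least 42-fold higher, and the T-box factor tbx-43 at least 54.4-fold. At the other end, wrt-1, a hedgehog-related gene of the epidermis, fell 19.1-fold from 10.27 ± 0.20 to 6.01 ± 0.31 (SD, n = 4, adjusted p = 3.06e-10), and the furrow collagen genes dpy-7 and dpy-2 fell 16-fold and 17.7-fold. In all, 8194 of 11833 probe sets changed in hc1, 5125 higher and 3069 lower, and of those that changed at least 2-fold 755 were higher and 1278 lower. The arrays of hc1 and wild type did not overlap for 64.9% of tested probe sets, against 2.86% by chance. That rate takes no account of the selection of arrays for their correlation.

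The balance of rises and falls depends on the scaling. The median of all tested probe sets shifted by 0.14 in hc1 and by 0.12 in hc24 on the log2 scale. Of the changed probe sets 62.5% were higher in hc1 and 63.5% in hc24, whereas cyclic loess gave 44% and 45.6% and median centring 76.5% and 80.4%. The median shift was 0.40 and 0.38 with median centring and -0.03 and -0.00 with cyclic loess. List tests, which compare a list with other genes, are less exposed to this. Calls lost or reversed by other scaling are named with their lists. Median centring added calls for histones in hc1 (adjusted p = 0.0411) and the male list in hc24 (adjusted p = 0.0353). Cyclic loess added respiratory chain genes in hc1 (median -0.19, adjusted p = 0.0176) and yolk genes in hc24 (median -0.30, adjusted p = 0.0397).

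Among 46 measured zygotic embryonic genes in hc1, 31 rose and 12 fell, with a median log2 change of 1.19 (adjusted p = 0.00404, and adjusted p = 0.294 with an estimated correlation). The list's call was lost with median centring (adjusted p = 0.0699) and without the filter on low values (adjusted p = 0.0547). The members went both ways: besides pes-10, the T-box gene tbx-38 rose 30.1-fold, from 4.43 ± 0.00 to 9.35 ± 0.13 (SD, n = 4), whereas hch-1, the hatching protease, fell 8.73-fold and the homeobox gene ceh-36 was at least 3.12-fold lower. Of 40 oocyte and eggshell genes 33 rose and 0 fell (median 0.40, adjusted p = 8.71e-05, and adjusted p = 0.394 with an estimated correlation). zif-1, which targets germ plasm proteins for degradation, rose 1.88-fold. Of 68 genes of mitosis and replication 60 rose (median 0.52, adjusted p = 2.49e-08, and adjusted p = 0.311 with an estimated correlation). They were led by the phosphatase gene cdc-25.3 (3.30-fold) and pcn-1, the replication clamp (1.82-fold). Of 34 meiosis genes 28 rose and 1 fell (median 0.40, adjusted p = 0.000733, and adjusted p = 0.346 with an estimated correlation), rad-51 rising 1.44-fold and spo-11 1.65-fold.

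The molting and larval cuticle list had the lowest median in hc1, with 26 of 30 genes lower and 1 higher (median -2.18, adjusted p = 8.0e-13, and adjusted p = 0.130 with an estimated correlation). ptr-4, a patched-related gene needed for molting, was at least 4.13-fold lower, and the cuticlin gene cut-3 fell 9.89-fold. nhr-23, a nuclear receptor of the molting cycle, was the member that rose, by 1.25-fold (adjusted p = 0.0339), with another of its probe sets in disagreement. That call was lost in 8 of 21 alternatives, 5 of them leaving out an array, and with cyclic loess the adjusted p was 0.405. Of 96 cuticle collagens 66 fell and 0 rose (median -0.43, adjusted p = 4.72e-11, and adjusted p = 0.346 with an estimated correlation). Of 48 body wall muscle genes 40 fell and 0 rose (median -0.95, adjusted p = 1.71e-13, and adjusted p = 0.274 with an estimated correlation). The troponin genes tnt-3 and tni-1 fell 8.81-fold and 5.29-fold, and the myosin heavy chain gene unc-54 fell 1.64-fold from 12.31 ± 0.07 to 11.59 ± 0.16 (SD, n = 4). Pharyngeal genes fell in 10 of 15 cases (median -0.90, adjusted p = 0.000579, and adjusted p = 0.294 with an estimated correlation), abu-13 by 15.1-fold. The list of dystrophin-complex and calcium-handling genes was fixed because ferlins include calcium-dependent membrane proteins of muscle. In it 22 of 38 fell and 9 rose (median -0.54, adjusted p = 0.000751, and adjusted p = 0.328 with an estimated correlation). The potassium channel gene slo-1 fell 5.21-fold and the annexin gene nex-3 fell 3.44-fold, while cav-1, a caveolin, rose 1.60-fold and pmr-1, a Golgi calcium pump, rose 1.41-fold.

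Of 23 neuronal genes in hc1 17 fell and 2 rose (median -0.61, adjusted p = 0.000130, and adjusted p = 0.274 with an estimated correlation), with the POU factor unc-86 falling 3.55-fold and the syntaxin unc-64 falling 2.29-fold. Of 39 neuropeptides and insulins 25 fell and 1 rose (median -0.62, adjusted p = 1.36e-05, and adjusted p = 0.328 with an estimated correlation), the exception being ins-34 at 2.19-fold. Of 35 intestinal genes 23 fell and 1 rose (median -0.48, adjusted p = 9.20e-06, and adjusted p = 0.311 with an estimated correlation), the aquaporin gene aqp-2 by 3.19-fold. Of the immune genes 60 fell, 18 rose and 26 did not pass (median -0.52, adjusted p = 1.19e-05, and adjusted p = 0.394 with an estimated correlation), a call lost without the filter on low values (adjusted p = 0.229). The lectin gene clec-196 fell 8.21-fold and irg-4 rose 4.99-fold. Detoxification genes fell in 45 of 87 cases and rose in 16 (median -0.39, adjusted p = 0.000440, and adjusted p = 0.346 with an estimated correlation), ugt-57 being at least 10.7-fold lower and cyp-34A9 3.38-fold higher. Lipid genes fell in 41 of 76 cases and rose in 11 (median -0.34, adjusted p = 1.36e-05, and adjusted p = 0.294 with an estimated correlation), with the carnitine palmitoyltransferase gene cpt-4 at least 6.95-fold lower. All 3 measured genes of male neurons and tail fell (median -1.07, adjusted p = 0.0177, and adjusted p = 0.311 with an estimated correlation). egl-46 fell 13.2-fold. Without the filter on low values the call was lost (adjusted p = 0.579).

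The remaining lists did not pass in hc1, apart from ribosomal proteins. Of 62 ribosomal protein genes 5 fell, with a median of -0.06 (adjusted p = 0.00863, and adjusted p = 0.514 with an estimated correlation). Median centring turned the median to 0.19, so no direction is drawn from it. The small heat shock gene hsp-12.1 fell 11.7-fold and hsp-43 fell 3.31-fold, while hsf-1, the heat shock transcription factor, rose 1.60-fold. Of the 37 heat shock and unfolded protein genes 14 rose and 13 fell (median 0.11, mean -0.62, adjusted p = 0.173). Histone genes rose in 24 of 41 cases and fell in 3 (median 0.32, adjusted p = 0.0602), with his-72 up 1.71-fold and his-35 down 1.64-fold. The gonadal sheath and spermatheca list had 5 rises and 6 falls among 16 (adjusted p = 0.509), the Notch ligand lag-2 being at least 5.61-fold higher and the junction gene ajm-1 falling 2.75-fold. Yolk genes had 1 fall among 6 (adjusted p = 0.454), DAF-16 and longevity targets 8 rises and 9 falls among 30 (adjusted p = 0.467), and respiratory chain genes 6 rises and 6 falls among 40 (adjusted p = 0.459).

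The comparison of hc24 with wild type showed the same early embryonic genes among the largest rises and molting-cycle genes among the largest falls. Major sperm protein genes passed as higher (adjusted p = 8.55e-05, and adjusted p = 0.568 with an estimated correlation) but were also high in hc1 replicate 2, and the list of other sperm genes did not pass (adjusted p = 0.287). pes-10 reached 8.71 ± 0.26 (SD, n = 4), at least 26.2-fold higher than wild type (adjusted p = 1.88e-12). dct-13 was at least 23.7-fold higher, pap-3 at least 23.6-fold and tbx-43 at least 44.5-fold. The cuticlin gene cut-3 dropped from 10.99 ± 0.31 to background (3.42 ± 0.52, SD, n = 4), at least 127-fold (adjusted p = 1.03e-10), ZK180.5 by at least 91.3-fold, the neuropeptide gene nlp-39 by at least 31.3-fold and the collagen gene col-165 by at least 135-fold. In all, 7034 probe sets changed, 4465 higher and 2569 lower, and 624 rose and 1127 fell at least 2-fold. The arrays of hc24 and wild type did not overlap for 55.2% of probe sets, against 2.86% by chance, again without account of that selection.

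All 27 measured major sperm protein genes rose in hc24, with a median log2 change of 3.58 (adjusted p = 8.55e-05, and adjusted p = 0.568 with an estimated correlation). These genes encode the cytoskeletal protein of nematode sperm and are nearly identical in sequence, so their probe sets cannot be read as independent genes. msp-78 rose 12.5-fold, from 7.99 ± 0.82 to 11.63 ± 0.16 (SD, n = 4, adjusted p = 0.00269). In hc1, 0 of 27 passed and the list did not pass (median 0.09, adjusted p = 0.723), but the arrays of that group did not move together. The mean log2 value of the list was 9.20 in hc1 replicate 2 and 5.16 to 6.03 in the 3 other hc1 arrays, beside 5.55 to 6.77 in wild type and 9.49 to 9.73 in hc24. Without hc1 replicate 2 the median was -0.83 in hc1 against wild type (adjusted p = 0.000596, and adjusted p = 0.530 with an estimated correlation, a test added after the results were seen), and the array means of the 2 groups overlap. Among 18 other sperm genes 11 rose and 2 fell in hc24 (median 0.42, adjusted p = 0.287), nspd-4 being at least 2.44-fold and the kinase gene spe-6 2.1-fold higher and ssp-37 1.60-fold lower. In hc1 3 of these rose and 3 fell (adjusted p = 0.836).

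**Figure D1:**
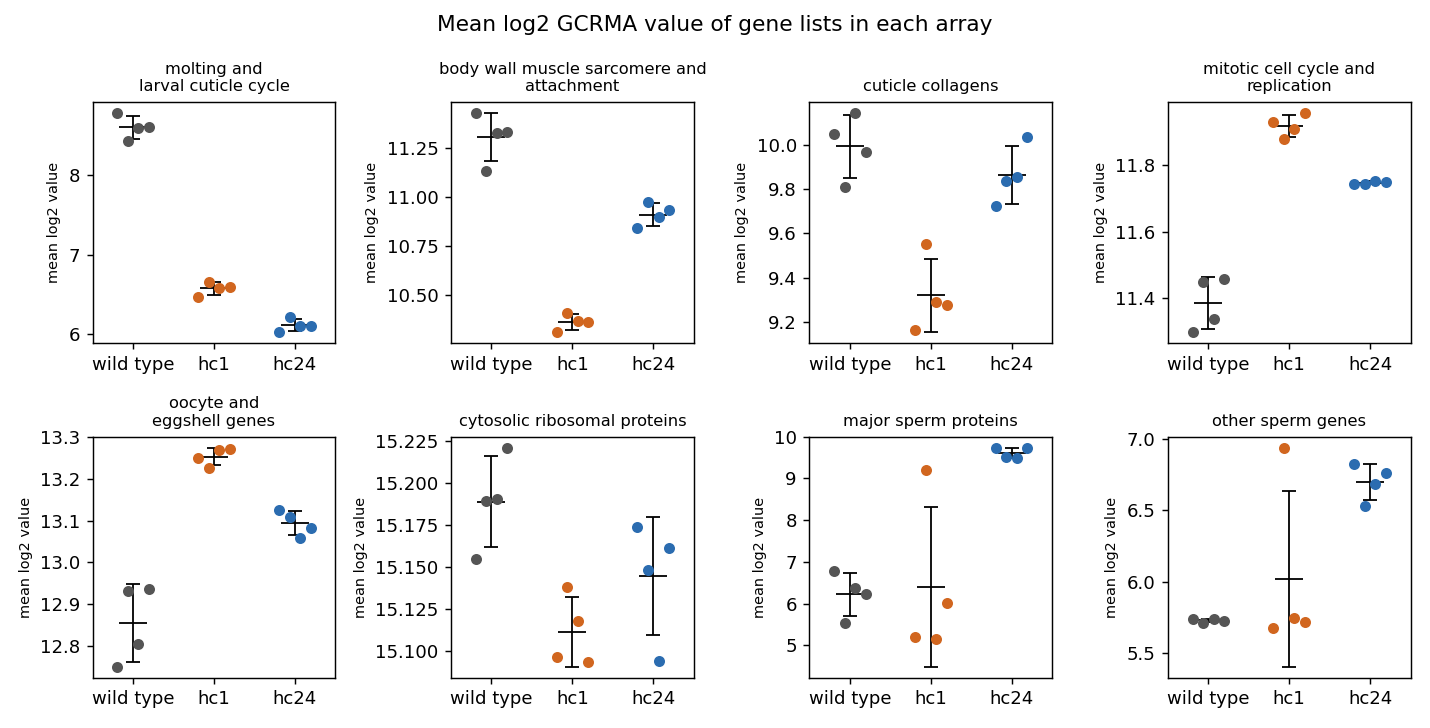
Mean log2 value of the measured members of 8 gene lists in each array (points), with the group mean and SD (bars, n = 4) for wild type, hc1 and hc24; the vertical axes are in log2 units, differ between panels and do not start at 0. The molting list lies at 8.43 to 8.78 in wild type, 6.47 to 6.66 in hc1 and 6.03 to 6.21 in hc24, and hc1 replicate 2, at 9.20, stands apart from its group in the major sperm protein list.

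The molting list fell in hc24 as in hc1, with 22 of 30 genes lower and 2 higher (median -2.76, adjusted p = 2.12e-12, and adjusted p = 0.130 with an estimated correlation). wrt-1 fell 65.0-fold, from 10.27 ± 0.20 to 4.25 ± 0.21 (SD, n = 4), while mlt-7, a peroxidase of cuticle formation, rose 1.94-fold and the hedgehog-related gene grd-3 rose 1.37-fold. Collagens went both ways: 28 of 96 rose and 14 fell (median 0.13, mean -0.13, adjusted p = 0.917). col-98 and col-103 rose 3.22-fold and 2.92-fold, and dpy-14 and dpy-2 fell 20.5-fold and 18.4-fold. Body wall muscle genes fell in 24 of 48 cases and rose in 2 (median -0.29, adjusted p = 9.40e-06, and adjusted p = 0.346 with an estimated correlation). tnt-3 and tni-1 fell 8.01-fold and 3.89-fold, whereas the members that rose were unc-54, by 1.50-fold to 12.89 ± 0.18 (SD, n = 4), and the hemicentin gene him-4, by 2.35-fold. Pharyngeal genes fell in 9 of 15 cases and rose in 2 (median -0.80, adjusted p = 0.00167, and adjusted p = 0.311 with an estimated correlation), abu-14 by 11-fold. Dystrophin-complex and calcium genes fell in 19 of 38 cases and rose in 7 (median -0.42, adjusted p = 0.000440, and adjusted p = 0.311 with an estimated correlation), slo-1 by 6.63-fold and nex-3 by 5.24-fold, while the sodium-calcium exchanger gene ncx-1 rose 2.03-fold.

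Zygotic embryonic genes rose in 26 of 46 cases and fell in 15 in hc24 (median 0.61, adjusted p = 0.0497, and adjusted p = 0.350 with an estimated correlation). This call was lost with median centring (adjusted p = 0.488), without the filter (adjusted p = 0.281), with values under 4 set to 4 (adjusted p = 0.0849), with array weights (adjusted p = 0.0615) and with the mean of probe sets (adjusted p = 0.0924). It was also lost without wild type replicate 5, wild type replicate 6, hc1 replicate 6 or hc24 replicate 5 (adjusted p = 0.0531, 0.0569, 0.0599 and 0.0763). tbx-38 rose 18.7-fold and hch-1 fell 23.2-fold. Oocyte genes rose in 25 of 40 cases and fell in 1 (median 0.22, adjusted p = 0.00948, and adjusted p = 0.568 with an estimated correlation), a call lost with cyclic loess (adjusted p = 0.0695), and egg-3 rose 1.36-fold. Mitosis genes rose in 53 of 68 cases and fell in 1 (median 0.34, adjusted p = 9.40e-06, and adjusted p = 0.346 with an estimated correlation), cdc-25.3 by 2.46-fold. Meiosis genes rose in 21 of 34 cases (median 0.24, adjusted p = 0.00634, and adjusted p = 0.439 with an estimated correlation). Respiratory chain genes rose in 20 of 40 cases (median 0.17, adjusted p = 0.0134, and adjusted p = 0.294 with an estimated correlation), for example gas-1 by 1.31-fold, and cyclic loess removed this call (median 0.03, adjusted p = 0.264).

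Neuronal genes fell in 14 of 23 cases and rose in 1 in hc24 (median -0.31, adjusted p = 0.000909, and adjusted p = 0.294 with an estimated correlation), unc-64 by 3.75-fold. Neuropeptides and insulins fell in 16 of 39 cases and rose in 4 (median -0.21, adjusted p = 0.00102, and adjusted p = 0.394 with an estimated correlation). flp-6 fell 9.98-fold. The call was lost without the filter (adjusted p = 0.0685). Intestinal genes fell in 17 of 35 cases and rose in 3 (median -0.20, adjusted p = 0.00169, and adjusted p = 0.394 with an estimated correlation). aqp-2 fell 5.35-fold and the cathepsin D gene asp-4 1.90-fold, while the cathepsin B gene cpr-5 rose 2.18-fold. Of the immune genes 58 fell, 24 rose and 22 did not pass (median -0.33, adjusted p = 1.36e-05, and adjusted p = 0.394 with an estimated correlation), abf-2, an antimicrobial peptide gene, by 20.8-fold, with clec-174 rising 6.41-fold. Without the filter the call was lost (adjusted p = 0.191). Heat shock and unfolded protein genes fell in 13 of 37 cases and rose in 3 (median -0.05, mean -0.67, adjusted p = 0.00386, and adjusted p = 0.274 with an estimated correlation), hsp-12.1 by 13.3-fold and hsp-43 by 4.11-fold. Lipid genes fell in 29 of 76 cases and rose in 16 (median -0.06, adjusted p = 0.0185, and adjusted p = 0.468 with an estimated correlation), fat-5, a fatty acid desaturase gene, by 3.54-fold. Ribosomal protein genes had 0 changes among 62 (median -0.05, adjusted p = 0.0326, and adjusted p = 0.593 with an estimated correlation), and median centring turned the median to 0.21. That call was lost without 3 of the arrays in turn. Lists that did not pass were histones with 19 rises and 4 falls among 41 (adjusted p = 0.110), yolk genes with 4 falls among 6 (adjusted p = 0.0605). Nor did DAF-16 and longevity targets with 6 rises and 13 falls among 30 (adjusted p = 0.0695), detoxification with 27 rises and 23 falls among 87 (adjusted p = 0.190), the gonadal sheath with 4 rises and 5 falls among 16 (adjusted p = 0.518) and male neurons and tail with 1 rise and 2 falls among 3 (adjusted p = 0.0793).

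The probe sets changed in both alleles numbered 3702 higher in both, 2160 lower in both and 231 in opposite directions. Independent lists of the same sizes would share 1934, 666 and 2271. Both comparisons use the same wild type arrays. In simulations of unchanged groups against those arrays, 0.02 probe sets on average were higher in both. With no probe set changed, almost none can be called. That count therefore does not show how much the shared arrays add to the overlap. With the wild type arrays divided between the comparisons, 2641 to 3139 were higher and 1805 to 1947 lower in both. The log2 changes correlated across probe sets with r = 0.854, against 0.501 in the simulations and 0.801 to 0.851 with divided controls, and their covariance was 0.826 against a simulated 0.0108. At the level of genes, 361 rose and 697 fell at least 2-fold in both alleles. The 6 largest common falls included T19C4.1 (at least 12.4-fold in each mutant), cutl-2, a cuticlin-like gene (at least 10.3-fold in each), and ugt-57.

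**Figure D2:**
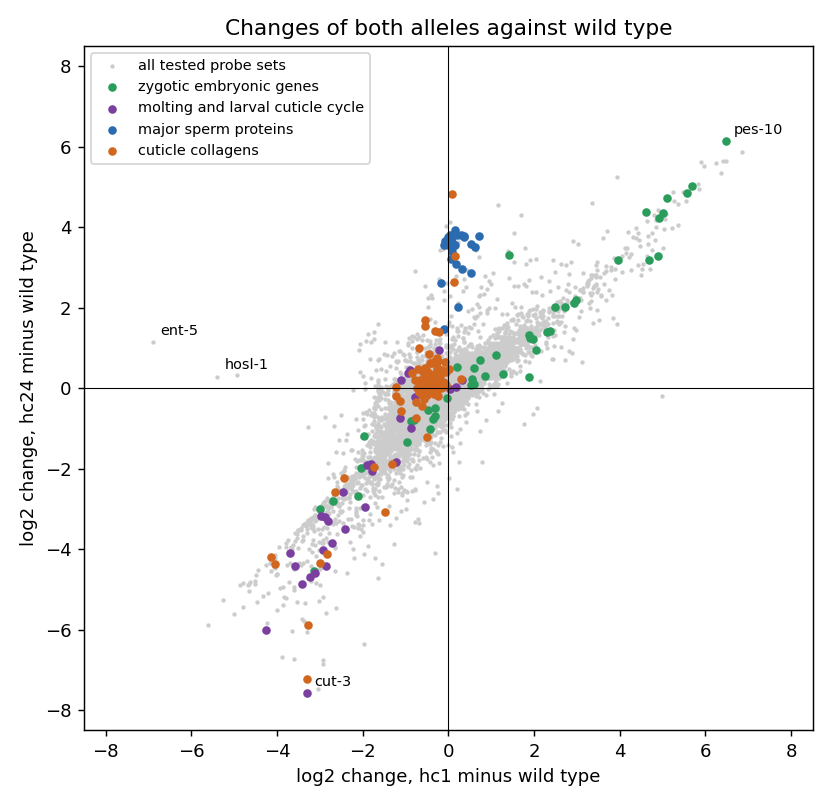
Log2 change against wild type of each tested probe set in hc1 (horizontal axis) and hc24 (vertical axis), with the brightest probe set of members of 4 gene lists in colour. Major sperm proteins lie near 0 for hc1 (median 0.09, or -0.83 without hc1 replicate 2) and around 3.58 for hc24, and ent-5 and hosl-1 are low in hc1 alone.

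Between the alleles, 3635 probe sets differed, 2197 higher and 1438 lower in hc1 than in hc24, and 257 and 404 of them at least 2-fold. The largest differences were ent-5 and hosl-1, low in hc1, and T22B7.7, high in hc1. ent-5, which encodes a nucleoside transporter, was at background in hc1 (1.69 ± 0.10) and at 8.59 ± 0.32 in wild type and 9.74 ± 0.16 in hc24 (SD, n = 4), at least 53.4-fold lower in hc1 than in hc24 (adjusted p = 4.25e-12). hosl-1, a gene of the hormone-sensitive lipase family, was at 2.32 ± 0.19 in hc1, 7.71 ± 0.22 in wild type and 8.0 ± 0.26 in hc24 (SD, n = 4), at least 16-fold lower in hc1 than in hc24 (adjusted p = 2.34e-10). These genes lie next to each other on chromosome X in the WBcel235 gene table, with 1 protein-coding gene between them for which no probe set was named. T22B7.7 was 36.7-fold higher in hc1 than in hc24 (10.03 ± 0.28 against 4.84 ± 0.23, SD, n = 4), nlp-39 at least 7.94-fold and cut-3 at least 12.9-fold.

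**Figure D3:**
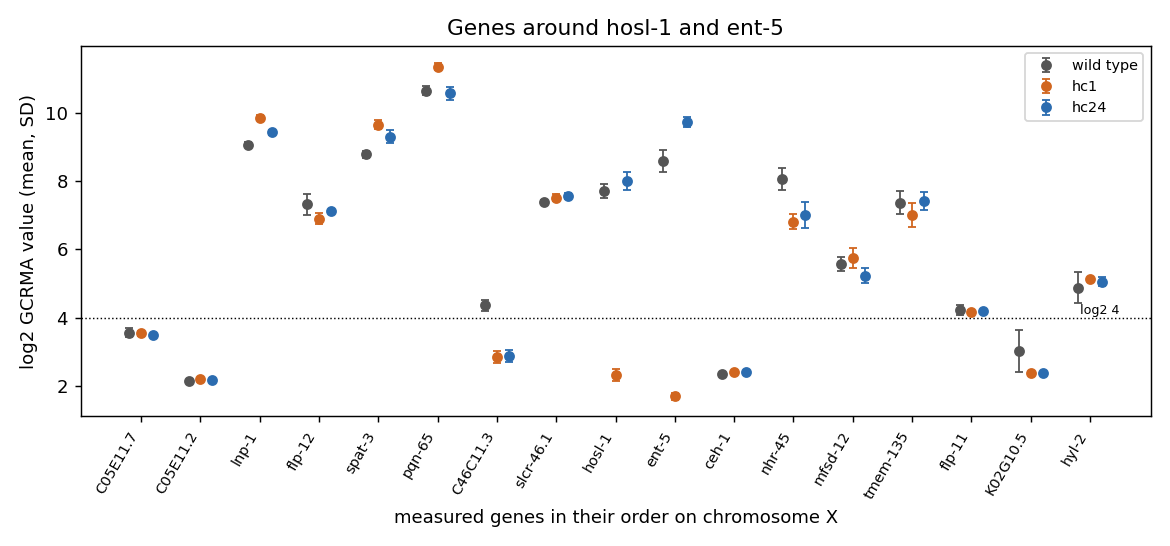
Log2 value (mean and SD, n = 4) of the brightest probe set of measured protein-coding genes on either side of hosl-1 and ent-5, in their order on chromosome X, with the spacing not to scale; the dotted line marks log2 4. Both genes lie under 4 in hc1 alone, at 2.32 and 1.69, while slcr-46.1 and nhr-45, the nearest genes on either side above background in wild type, lie at 7.52 and 6.81 in hc1.

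By list, hc1 was lower than hc24 in major sperm proteins (27 of 27, median -3.41, adjusted p = 7.53e-13, and adjusted p = 0.346 with an estimated correlation). msp-76 and msp-38 were 13.7-fold and 13.6-fold lower. Without hc1 replicate 2 the median was -4.42. Other sperm genes were lower in 6 of 18 cases and higher in 1 (median -0.43, adjusted p = 0.00368, and adjusted p = 0.294 with an estimated correlation). Without hc1 replicate 2 the median was -0.48, with adjusted p = 0.0495 at an estimated correlation. Collagens were lower in hc1 in 60 of 96 cases and higher in 6 (median -0.58, adjusted p = 5.77e-18, and adjusted p = 0.294 with an estimated correlation). col-129 was 26.7-fold lower, at 5.27 ± 2.16 against 10.02 ± 0.17 (SD, n = 4), with hc1 replicate 2 at 8.49 and a log2 difference of -5.81 without it. Body wall muscle genes were lower in hc1 in 29 of 48 cases and higher in 1 (median -0.60, adjusted p = 1.71e-13, and adjusted p = 0.274 with an estimated correlation), unc-54 by 2.47-fold and him-4 by 3.87-fold. Respiratory chain genes were lower in 15 of 40 cases (median -0.15, adjusted p = 4.07e-07, and adjusted p = 0.0900 with an estimated correlation), asg-2 by 1.56-fold. Detoxification (36 lower and 13 higher of 87, median -0.12, adjusted p = 0.000122, and adjusted p = 0.346 with an estimated correlation), lipid (26 lower and 14 higher of 76, median -0.05, adjusted p = 0.000883, and adjusted p = 0.346 with an estimated correlation) and intestinal genes (15 lower and 10 higher of 35, median -0.15, adjusted p = 0.00442, and adjusted p = 0.442 with an estimated correlation) also passed. sams-1, the S-adenosylmethionine synthetase, was 9.30-fold lower in hc1 than in hc24.

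hc1 was higher than hc24 in zygotic embryonic genes (30 of 46 higher and 3 lower, median 0.48, adjusted p = 1.36e-05, and adjusted p = 0.135 with an estimated correlation, or 0.0495 when hc1 replicate 2 is also left out), in mitosis genes (19 of 68 higher, median 0.15, adjusted p = 0.000662, and adjusted p = 0.442 with an estimated correlation) and in oocyte genes (11 of 40 higher, median 0.17, adjusted p = 0.00404, and adjusted p = 0.528 with an estimated correlation). cdc-25.3 was 1.34-fold higher in hc1. The molting list was higher in hc1 in 13 of 30 cases and lower in 6 (median 0.29, adjusted p = 0.0410, and adjusted p = 0.489 with an estimated correlation), a call lost without the filter (adjusted p = 0.118), with values under 4 set to 4 (adjusted p = 0.0811), with array weights (adjusted p = 0.0615) and without hc1 replicate 6 or hc24 replicate 1 (adjusted p = 0.0628 and 0.0644). Ribosomal protein genes had 1 lower among 62 (median -0.02, adjusted p = 0.0497, and adjusted p = 0.613 with an estimated correlation), and leaving out any of 7 arrays ended that call, with adjusted p up to 0.133, as did median centring and values under 4 set to 4. The other 12 lists did not pass, with adjusted p from 0.0822 for neurons to 0.835 for histones; these include dystrophin-complex and calcium genes (5 higher and 2 lower of 38, median 0.01, adjusted p = 0.535).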

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

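The tests of RNA quality, of the sperm signal and of hosl-1 and ent-5 were chosen only after those results had been seen; the tests of embryos, stage, males, chromosome I and other splits of the arrays were written before. The condition that a list whose members go both ways decides nothing was added afterwards, and the test of sperm genes outside the family replaced earlier forms whose results had been seen. For each contrast, 1 of the 35 splits of the 8 arrays into 4 and 4, the real one, gave as many changed probe sets: 8030 in hc1 against wild type, 6726 in hc24 against wild type and 3838 in hc1 against hc24 when only those 8 arrays were fitted, with at most 0 in any other split. The arrays had been kept for their correlation within the genotype, which favours the real split beforehand. These splits therefore cannot exclude chance.

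The change common to both alleles, with most molting genes low and most early embryonic and germ line genes high, was set against technical explanations, although 0 of 25 lists passed with an estimated correlation (lowest adjusted p = 0.130). RNA quality is not decided. The 3' minus 5' signal of 5 worm control transcripts differed from wild type by at most 0.36 (exact p = 0.0571). That lies below 0.5 times the molting medians, but this bound was chosen after the results were seen. A difference of 0.36 also lies between the medians of the oocyte list, 0.40 in hc1 and 0.22 in hc24. The signal therefore cannot argue against RNA quality as a part of the changes. Fewer embryos in the mutants stays open: the medians of the zygotic embryonic list, 1.19 in hc1 and 0.61 in hc24, exceeded the bounds of 0.48 and 0.42 set beforehand, but those bounds were wrong for a list of which 12 members fell in hc1 and 15 in hc24. A difference in developmental stage within the young adult gate could account for the molting list, whose median nearer to 0 was -2.18 and which fell in both mutants. Stage, strain background and the fer-1 alleles themselves cannot be told apart further here, because each genotype is a strain of its own, and a direct effect of fer-1 on these genes stays open and untested.

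For the major sperm protein signal, high in all hc24 arrays and in hc1 replicate 2, cross-hybridization within that gene family alone is not settled. The mean of 16 other sperm genes was at least 6.80 in those 5 arrays and at most 6.17 in the other 7. That is a gap of 0.63 with SD up to 0.12, though the full list of 18 did not pass in hc24 (adjusted p = 0.287). The gap rested on probe sets marked as shared, here only those with the suffix _x_at. The 9 genes whose probe sets are not marked as shared gave a gap of -0.0877. Marked probe sets could carry signal from related genes, so the gap cannot exclude cross-hybridization in this family or in others. A mislabelled hc1 replicate 2, or one mixed with hc24 worms, is argued against because its hosl-1 and ent-5 probe sets reached at most 2.42, as in the other hc1 arrays, while no hc24 array was under 6.98. A place of hc24 nearer to the last molt would predict a higher molting list there. The hc24 mean instead differed by -0.44 from that of the 3 other hc1 arrays. Each hc24 array (6.03 to 6.21) lay under each hc1 array (6.47 to 6.66), which goes against that place. It still stays open, as members went both ways, 13 higher and 6 lower in hc1. Males stay open too. In hc24 the median of the male list was -1.16, opposite to the sperm signal, which the bound set beforehand took as evidence against males. That bound was written for the change common to both alleles and wrongly took a list that does not pass as an absence. Moreover, 3 of 17 members of the male list were measured and went both ways in hc24 (adjusted p = 0.0793). More sperm or spermatocytes per worm in these 5 cultures may account for the signal, as a hypothesis that was not tested. The mean of the 9 genes not marked as shared was 6.95 in hc1 replicate 2, within the 6.93 to 7.03 of the other hc1 arrays. They thus show no rise in that culture over the other hc1 arrays. In hc24 they reached at least 7.03 beside at most 6.88 in wild type. The other hc1 arrays, which lack the sperm signal, also lay above wild type, so this excess does not follow that signal. The reason why 1 hc1 culture resembles hc24 stays open.

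hosl-1 and ent-5 were at background in hc1 alone: a scan of 9529 probe sets that were at least at log2 6 in all wild type and hc24 arrays found 3 under log2 4 in all hc1 arrays, and these were the 2 probe sets of hosl-1 and the 1 of ent-5. Background in a lone strain is not particular to this pair, as 22 probe sets were so in wild type alone and 5 in hc24 alone, cut-3 and nlp-39 among them. Failed or polymorphic probes of a lone probe set are argued against, since all 3 were low. A variant of the hc1 strain that removes both genes is a candidate explanation: among 6970 genes expressed in the other strains, a random pair lies as close in gene order with a chance of 0.000282. A loss of expression without a loss of DNA stays open, as no sequence of the strain was analysed here.

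Some genes moved in opposite directions in the alleles, with both changes and the difference past the threshold. The log2 difference of hc1 minus hc24 was -8.05 for ent-5, -3.22 for sams-1, -2.24 for col-98, -2.09 for col-103, -1.95 for him-4, -1.35 for grd-3, -1.30 for unc-54, -1.26 for pgal-1, -1.17 for col-34 and -0.64 for asg-2, and it was 2.65 for cyp-34A9 and 1.72 for mtl-1. The rise of col-34 in hc24 was lost in 9 of 21 alternatives, with adjusted p up to 0.146, and 1 alternative each removed the change of asg-2 in hc1 (adjusted p = 0.526) and in hc24 (adjusted p = 0.0705).

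Changed genes between the alleles were not concentrated on chromosome I, where fer-1 lies. The odds ratio of a Fisher exact test was 0.678 with an upper confidence bound of 0.769. Chromosome III had a similar odds ratio of 0.691, whereas chromosome X had 2.36. The test covers only where the changed genes lie. It cannot decide whether variants linked to fer-1 act on genes elsewhere. Of 213 tested probe sets with no gene in the table used, 85 changed in both alleles with the same sign, 56 up and 29 down. That is 39.9%, below the 49.5% of all tested probe sets.

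In 37 of 402 group values tested, 9.20% where chance gives about 5%, a lone sample stood apart relative to the spread of the other 3 of its group, and 7 of the 37 were hc1 replicate 2 and 5 hc24 replicate 5. The values tested are those of 96 genes chosen after the results were seen, not all of them named elsewhere, of the gene list means and of array quality measures. The distance to the nearest other array was under 0.5 log2 in 25 of the 37 and as small as 0.04, and 13 lay under log2 4, so most are small in size. In hc1 replicate 2 the log2 value was 8.49 for col-129, 5.62 for nspd-4, 5.18 for him-4, 12.80 for aqp-2, 9.38 for dod-3 and 4.2 for msp-74, and the mean of the other sperm genes was 6.94, beside 5.67 to 5.75 in the other hc1 arrays. In the further hc1 arrays it was 2.09 for ptr-4 and 4.67 for tnt-3 in replicate 1, 2.64 for T19C4.1 in replicate 5 and 3.18 for ugt-57 in replicate 6. In wild type, replicate 3 had a detoxification mean of 8.20, 12.73 for cyp-13A5 and -1.23 for the 3' minus 5' signal of gly-14, and replicate 4 had 10.52 for cut-3, 7.03 for T22B7.7 and a pharyngeal mean of 6.74. Wild type replicate 5 had 3.06 for pap-3, 5.84 for ceh-36 and 2.70 for lag-2, and replicate 6 had 3.21 for tbx-43. In hc24, replicate 1 had 2.42 for cutl-2, 3.59 for abu-13 and 3.06 for cpt-4, and replicate 2 had 8.72 for pap-3, 6.97 for hch-1, 3.93 for wrt-1 and 5.18 for T22B7.7. hc24 replicate 3 had 1.90 for ptr-4, 8.26 for ins-34, 9.53 for clec-174 and 7.67 for his-71, and replicate 5 had 3.06 for T19C4.1, 2.64 for cut-3, 13.18 for asp-4, 8.73 for ssp-37 and 12.04 for gas-1.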

How the results depend on the processing

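All alternatives but 1 were chosen before the data were examined, and which of their values are printed was decided after the results were seen. Probe sets changed in hc1 against wild type rose from 8194 to 12514 without the filter on low values, and 72.4% of these were higher. More probe sets were tested there. In hc24 against wild type the same step gave 8256 against 7034, so the number tested does not alone account for the rise in hc1. Restricted to at least 2-fold, the counts were 2033 for hc1 against wild type, 1751 for hc24 against wild type, 661 between the alleles and 1346 in the same direction in both, and 37.1%, 35.6% and 38.9% of the changed probe sets were higher in these contrasts. No gene list passed with an estimated correlation (0 in each contrast, against 17, 17 and 13). With hc1 replicate 2 also left out, an alternative added after the results were seen, 0, 0 and 2 passed, other sperm genes and zygotic embryonic genes between the alleles (adjusted p = 0.0495 each). The median of the ribosomal protein list reversed with median centring, to 0.19 in hc1 (adjusted p = 0.510) and 0.21 in hc24 (adjusted p = 0.272). Centring adds the difference between array medians, 4.60 in wild type and 4.35 in each mutant, to every change. The reversal is therefore not particular to ribosomal protein genes. The median of all tested probe sets in hc1 against wild type was 0.04 without the filter.

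Leaving out each array in turn gave 7630 to 8253 changed probe sets in hc1 against wild type, 6378 to 7072 in hc24 against wild type, 2886 to 3804 between the alleles and 5204 to 5910 in both. Some arrays share a replicate number across genotypes. Their deviations from the group means correlated at -0.0748 to 0.0825, so the numbers do not pair the arrays. With the number as a replicate block the counts were 7353, 6508, 2997 and 5410. Of the values of 96 genes under alternatives, 5827 kept their direction and side of the threshold, 89 lost it, 47 gained it and 67 without a call moved. Of those of gene lists, 1610 kept it, 128 lost it, 32 gained it, 28 moved and 2 reversed. Without wild type replicate 4, T22B7.7 was 5.66 higher in hc1 than in wild type, against 5.00. Signals under log2 4 limit what can be said of weak genes, fer-1 among them.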

Other observations

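The classes and chromosomes described here were chosen after the data were seen. Genes were grouped by the class in their name, which gave 117 classes with at least 8 measured genes, tested for genes changed at least 2-fold in both alleles with a Fisher test and Benjamini-Hochberg adjustment over 234 tests. That test takes the genes of a class as independent. Members of a class can change together or share probe signal, so the p-values of classes are lower than the data support. The F-box class fbxb stood out with 35 of 47 genes up (adjusted p = 5.10e-37) and medians of 2.58 in hc1 and 1.60 in hc24. sdz genes, named for SKN-1-dependent zygotic expression, were up in 12 of 18 cases (adjusted p = 3.48e-11), T-box genes in 5 of 9 (adjusted p = 0.000594), skr genes, which encode Skp1-related partners of F-box proteins, in 7 of 18 (adjusted p = 0.000319), fbxc genes in 7 of 19 (adjusted p = 0.000365) and btb genes in 5 of 10 (adjusted p = 0.000957). Homeobox genes of the ceh class went both ways, with 7 of 26 up (adjusted p = 0.00186) and 6 down (adjusted p = 0.198). Down in both alleles were 16 of 65 unc genes (adjusted p = 0.00116), 7 of 17 hsp genes (adjusted p = 0.00487), 5 of 10 grl genes (adjusted p = 0.0132), 5 of 11 cutl genes (adjusted p = 0.0206), 5 of 12 clc genes (adjusted p = 0.0302) and 4 of 8 each of fkb and vab genes (adjusted p = 0.0358).

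Genes on chromosome X changed more often than others. In hc1 against wild type 77.2% of them changed (odds ratio 1.54, Fisher exact test, adjusted p = 9.26e-09), in hc24 66.1% (odds ratio 1.34, adjusted p = 2.00e-05) and between the alleles 49% (odds ratio 2.36, adjusted p = 1.48e-40). Neighbouring genes are not independent, so these p-values are lower than the data support.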
